A study of Mus musculus with 3 samples.

How the data were processed

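Lung RNA of female C57BL/6 mice was measured on 3 arrays, 1 per group: a Th17 model, a Th2 model and a saline control. Per the labels' protocols, total RNA was extracted with Trizol and labelled with Cy3, and each array was read in 1 colour. The labels do not say whether an array holds RNA of a single mouse or of several. Each array carried 148260 spots, of which 143286 were not control spots and belonged to 91188 probes. Of these probes, 39410 lay on 1 spot, 51738 on 2 spots and 40 on 10 spots. The probes on 2 spots were named A_30 or mmu. Of the probes named A_51 to A_66, 39410 lay on 1 spot and 0 on 2 spots.

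Per the file headers, the spots were quantified with Agilent Feature Extraction 10.7.1.1, and the processed intensity of each spot is on a linear scale, background-subtracted and detrended within the array. The mean intensity of each spot and the median intensity of its local background were deposited beside it, per the file headers, with no correction. The same files hold 0 or 1 marks for spots well above background, saturated spots and outlier spots, set by the authors' scanner software. The deposited value table holds log2 values of the same arrays for 91168 probes, with a median of 4.25 in each column. Its columns hold nearly the same sorted values, with a median difference of 0.0004 at the same rank, so its scale is quantile-normalized log2. The sources used here do not give the steps that made it. Its columns were matched to the scanner values of their own arrays, with a rank correlation of 0.9998 across probes in each.

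The values reported are log2 of the processed intensity minus the array's 75th percentile over all non-control probes. Spots marked as non-uniform or as population outliers were left out, 35 on the Th17 model array, 49 on the Th2 model array and 73 on the control array. The remaining spots of a probe were averaged on the log2 scale. A probe counted as detected where at least 50% of its spots were well above background. The probe was compared where it was detected on at least 1 of the 2 arrays. The other array then took the higher of its own value and the lowest value among the array's detected probes, as the design fixed it. The difference is a lower bound only where the array that detected the probe is the higher one. Where the raised value lies above the detected one, the difference is no bound, and the counts without such differences are given beside the others. No spot was saturated. The number of arrays limits the precision: with 1 array per group there was no spread between samples, no test and no p-value, and every difference describes these arrays. The only error at hand is technical, from spots of the same probe on 1 array. Probes past 2-fold were counted in each comparison, with the same counts over probes detected on both arrays beside them.

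The gene name and systematic name columns repeat the probe name for every non-control probe, and 0 of the 91188 names matched the gene tables used here, so the files do not pair probes with genes. The rule for named genes, written before the data were examined, took the 12 genes with the largest differences in each direction and members of fixed gene lists, and could not be applied. In its place, the 2 probes with the highest and the 2 with the lowest difference in each comparison are named by their IDs, among probes detected on both arrays. The 45 gene lists fixed before the data were examined, with 776 genes, were not run for the same reason. The comparison of long noncoding RNAs with their nearest genes was not run either, because neither coordinates nor gene names pair with the probes. The control probes that carry the names of Gapdh and Pgk1, on 10 spots each, were chosen after their values were seen, and so were the 3 families of probe names. Which family holds long noncoding RNA is not given in the sources used here.

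The 2 model arrays lay on slide 1 and were read in scan 1, and the control array lay on slide 2 and was read in scan 2. Slide and control therefore cannot be told apart in the comparisons with the control. The Th17 model against Th2 model comparison lies within 1 slide.

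Overlap between the models was set beside 100 simulated sets of 3 arrays with no effect that share a control, drawn with the spot noise of the arrays or with the Th2 model against control differences taken as noise. The steps were tested on simulated data before use. In a copy of the control array with spot noise, run on 91177 probes, 60% of 40 probes changed 2-fold came out past 2-fold, against 5% of 40 changed 1.5-fold and 100% of those changed 3-fold, 4-fold or 8-fold. Of 63823 unchanged probes, 1.6% came out past 2-fold. The changed probes left out the dimmest detected ones. Both simulated arrays took the control array's detection marks and its spot noise from probes on 2 spots. In the dimmest of 5 groups, 17.19% of spot pairs on the Th17 model array differed at least 2-fold, against 3.93% on the control array. These rates may therefore be too favourable for the real comparisons.

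The alternatives written before the data were examined were quantile normalization, centring on the median or the 75th percentile of probes detected on all arrays, normexp background correction (offset 50), no background correction, only probes detected on both arrays, no filter on dim probes, outlier spots kept, the deposited value table, centring on spike-in probes, a 4-fold threshold and saturated probes left out. A higher floor, bounds counted only in the direction of detection, a stricter definition of a detected probe and the brighter 50% of probes were added after seeing the data. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.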

Results

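Gene expression was measured in mouse lung on an array of long noncoding RNA and mRNA probes, in 2 models of asthma and a control. The Th17 model, in which neutrophils predominate in the airway inflammation, was made with 100 ug of house dust mite, 100 ug of ovalbumin and 15 ug of lipopolysaccharide. The Th2 model, in which eosinophils predominate, was made with 25 ug of ovalbumin, and control mice received saline. House dust mite and ovalbumin are allergens, and lipopolysaccharide is a bacterial cell wall component that activates innate immunity. Each group had 1 array, so no difference has a replicate check and no p-value is given. The control array was the brightest, with a 75th percentile of intensity of 117.4, against 84.9 on the Th2 model array and 68.9 on the Th17 model array. Of the 91188 probes, 64023 (70.2%) were detected on the control array, 54082 (59.3%) on the Th2 model array and 49038 (53.8%) on the Th17 model array. All 3 arrays detected 46538 probes, and 9131 were detected on the control array only, against 707 on the Th17 model array only and 715 on the Th2 model array only. The spots of probes printed on 2 spots differed by a median SD of 0.147 log2 on the Th17 model array, 0.133 on the Th2 model array and 0.134 on the control array. Of these pairs, 6.99%, 5.7% and 5.95% differed by at least 2-fold. These values come from A_30 and mmu probes, as 0 of the A_51 to A_66 probes lie on 2 spots. Of 10 quality measures in the files, 0 were out of range on the Th17 model array, 3 on the Th2 model array and 4 on the control array. The files give a median CV between replicate spots of 5.81%, 8.38% and 8.26% on these arrays.

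The first comparison asked how lung expression in the Th17 model differed from the control. Among the 48197 probes detected on both arrays, 3497 were at least 2-fold higher and 2667 at least 2-fold lower in the Th17 model, 12.8% in all. The probe A_51_P202331 was highest, 1653-fold above the control, with an intensity of 13531.6 against 13.9. A_51_P110341 followed at 523-fold, with an intensity of 58874.3 against 191.8. Each of these probes lies on 1 spot, so their folds have no check between spots. The probes mmu_12354_PI428960544 and mmu_2823_PI428960544, on 2 spots each, were 12.8-fold and 12.5-fold lower. These folds depend on the background: with normexp correction the differences of the 4 probes, in the same order, were 8.01, 8.29, -1.78 and -1.97 log2, against 10.69, 9.03, -3.67 and -3.64. Among probes detected on both arrays, 21 were at least 16-fold higher and 0 at least 16-fold lower, and 267 were at least 4-fold higher and 100 lower. Among probes detected on 1 array only, 41 were at least 16-fold higher and 5 at least 16-fold lower as bounds, and 22 and 2 with a higher floor. With probes detected on 1 array included, 4738 of 64851 probes lay past 2-fold on the higher side and 5611 on the lower side. Of the 4738, 443 were detected on the control array only, so they are no bounds, and 4295 remained without them. This split turned with the floor, as a higher floor gave 7575 higher and 3313 lower probes, or 4131 and 3313 with bounds only in the direction of detection. Normexp correction gave 515 higher and 979 lower probes. Of the 23809 probes on 2 spots that were detected on both arrays and had no spot marked as an outlier on any array, 71.1% had spots that did not overlap between the arrays, against 33.3% by chance. That reference covers spot noise. It covers neither the spread between separate samples nor an offset between the arrays. These probes on 2 spots are A_30 and mmu probes only, so the share does not cover A_51 to A_66 probes. The slide of the control cannot be told apart from the group here, and centring on the spike-in probes gave 278 higher and 53935 lower probes. Without background correction, 1445 probes were at least 2-fold higher and 1287 lower.

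The second comparison asked how lung expression in the Th2 model differed from the control. Among the 53233 probes detected on both arrays, 788 were at least 2-fold higher and 277 at least 2-fold lower, 2.0% in all. In the simulated copy of the control array, spot noise alone put 1.6% of 63823 unchanged probes past 2-fold, over a different set of probes. Among the 46538 probes detected on all arrays, simulated spot noise gave 112.3 higher and 111.9 lower probes, against 408 and 205 observed. Spot noise may therefore account for a large part of these counts. The probe A_55_P2114367 was highest, 32.2-fold above the control, with an intensity of 305.7 against 13.1, and A_51_P266876 was 10.9-fold higher. With normexp correction these differences were 2.6 and 1.36 log2, against 5.01 and 3.45. Each of these probes lies on 1 spot, so their folds have no check between spots. The probe mmu_12354_PI428960544 was 10.8-fold lower, and among probes detected on both arrays it was the lowest here and in the Th17 model against the control. Both differences rest on 1 value of the shared control array, with an intensity of 370.6 against 24.9 in the Th2 model and 17.1 in the Th17 model, and the models differed by -0.25 log2. A_55_P1997791, also on 1 spot, was 9.0-fold lower, and with normexp correction the 2 lower probes differed by -1.84 and -1.81 log2, against -3.43 and -3.17. Differences of at least 4-fold were found for 28 higher and 21 lower probes, and 1 higher probe passed 16-fold. Among probes detected on 1 array only, 4 were at least 16-fold higher and 4 at least 16-fold lower as bounds, and 1 and 2 with a higher floor. With probes detected on 1 array included, 1648 of 64855 probes lay past 2-fold on the higher side and 1147 on the lower side, a share of higher probes of 59.0%. Of the 1648, 130 were detected on the control array only, so they are no bounds, and 1518 remained without them. This split turned with the scaling: quantile normalization gave 1076 higher and 1705 lower probes, the authors' deposited values gave 1205 and 1399, and centring on the spike-in probes gave 457 and 8361. A higher floor moved the split the other way, to 2887 higher and 432 lower probes, or 1187 and 432 with bounds only in the direction of detection. Without background correction, 137 probes were at least 2-fold higher and 140 lower. Normexp correction gave 22 higher and 99 lower probes, and the brighter 50% of the probes detected on both arrays gave 33 and 98, so the excess of higher probes lay among dim probes. Of the 27919 probes on 2 spots that were detected on both of these arrays and had no spot marked as an outlier on any array, 55.4% had spots that did not overlap, against the same 33.3% by chance from spot noise. This share again holds A_30 and mmu probes only. The 33.3% also allows for no offset between the arrays. Here the median difference was 0.04 log2 for A_30 probes, 0.11 for mmu probes and 0.35 in the dimmest of 10 brightness groups. Such offsets can raise the share without any effect of the model.

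The third comparison set the models against each other on 1 slide. Among the 46672 probes detected on both arrays, 2051 were at least 2-fold higher and 3310 at least 2-fold lower in the Th17 model, 11.5% in all. A_51_P110341 was 363-fold higher in the Th17 model than in the Th2 model, and mmu_31471_PI428960544, on 2 spots, was higher by 6.75 log2. A_55_P2114367 was 13.4-fold lower and A_51_P367866 was 12.1-fold lower. Like A_51_P110341, these probes lie on 1 spot each, with no check between spots. With normexp correction the 4 differences were 7.97, 6.32, -1.98 and -1.86 log2, against 8.5, 6.75, -3.75 and -3.59. Differences of at least 16-fold were found for 19 higher and 0 lower probes detected on both arrays, and as bounds for 36 higher and 2 lower probes detected on 1, or 19 and 0 with a higher floor. With probes detected on 1 array included, 3272 of 56436 probes lay past 2-fold on the higher side and 6364 on the lower side, a share of higher probes of 34.0%, and 2 of the 3272 were detected on the Th2 model array only. Taking the 75th percentile over probes detected on all arrays gave 2325 higher and 7997 lower probes, centring on the spike-in probes 334 and 29326, and no background correction 715 and 1109. The first of these scalings moved the median difference by -0.13 log2. Across the 46538 probes detected on all arrays, which are not independent replicates, the levels of the Th2 model and the control correlated with a Pearson r of 0.986, against 0.953 for the Th17 model with either.

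**Figure D1:**
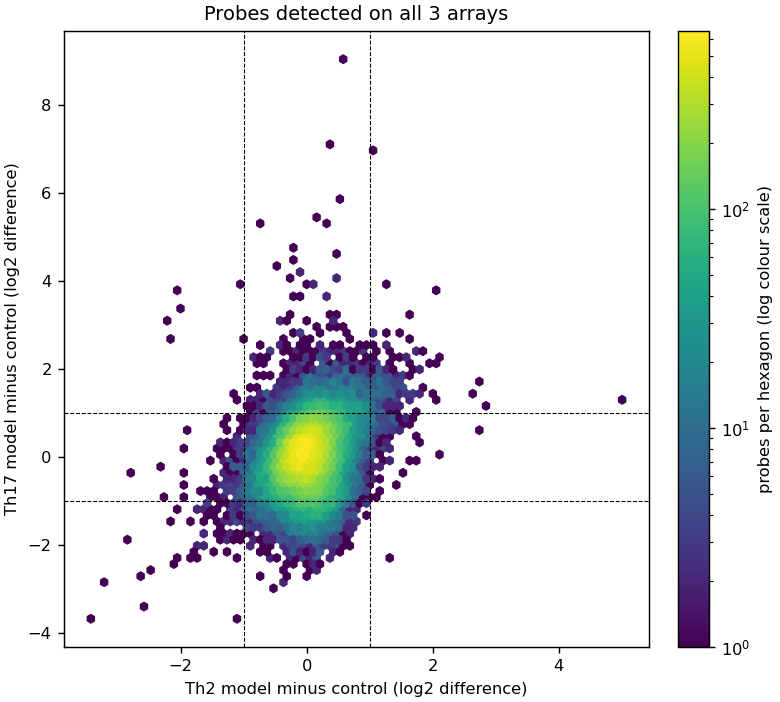
Log2 difference of the Th17 model from the control (vertical axis) against that of the Th2 model from the control (horizontal axis) for the 46538 probes detected on all 3 arrays, with the number of probes per hexagon as colour on a log scale and dashed lines at 2-fold. Both models were at least 2-fold higher for 254 probes and at least 2-fold lower for 76, on 1 array per group and 1 shared control array.

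Probes past 2-fold in both models were counted among the 46538 probes detected on all arrays. Of the 408 probes at least 2-fold higher in the Th2 model, 254 (62.3%) were also at least 2-fold higher in the Th17 model. Of the 205 probes at least 2-fold lower in the Th2 model, 76 (37.1%) were also lower in the Th17 model. Independent lists of these sizes would share 25 higher and 11.7 lower probes. In simulated arrays with no effect, a shared control and spot noise, lists of 242.4 (Th17 model) and 112.3 (Th2 model) higher probes shared 24, and lists of 245.4 and 111.9 lower probes shared 25. With the Th2 model differences taken as noise, lists of 152.6 and 150.5 higher probes shared 18.9, and lists of 154.2 and 151.1 lower probes shared 19.5. The observed Th17 model lists held 2846 higher and 2661 lower probes, so the simulated lists give no chance value for the observed shares. The models share 1 control array, which cannot be split, so part or all of the excess over independent lists may come from it. In the dimmest of 10 brightness groups, both models also lay above the control, by medians of 0.47 log2 (Th17 model) and 0.35 (Th2 model). Independent lists do not allow for such an offset. In opposite directions, 7 probes were higher in the Th17 model and lower in the Th2 model, and 1 the other way. With probes detected on 1 array included, 482 probes lay past 2-fold on the higher side and 514 on the lower side in both models, and 366 and 514 with bounds only in the direction of detection. These counts came to 18 and 67 without background correction, 3 and 44 with normexp correction, and 14 and 7865 with centring on the spike-in probes. The balance turned the other way with a higher floor, at 2203 and 189, and with no filter on dim probes, at 10307 and 1218. The 2203 include differences that are no bounds.

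The control probes named for Gapdh and Pgk1, enzymes of glycolysis, were the only probes of lung RNA with a gene name that was used. These probes were chosen after their values were seen. In the Th17 model, Mouse-PGK1_5 was 2.81-fold higher than in the control and Mouse-PGK1_3 was 2.04-fold higher. Mouse-GAPDH_3 was 1.8-fold higher and Mouse-GAPDH_5 was 1.59-fold higher. Before scaling, the Mouse-GAPDH_3 intensity was 1696.5 against 1608.3 in the control, and that of Mouse-GAPDH_5 was 8044.8 against 8595.1. The Gapdh differences therefore rest on the scaling. For Mouse-PGK1_3 and Mouse-PGK1_5 the intensities were 1132.3 against 946.8 and 255.8 against 155.2. Centring on the spike-in probes turned all 4 of these differences to lower. That centring used the mean of 6 spike-in probes, whose own shifts before scaling ran from 0.3 to 1.26 log2. The -0.14 log2 it gave for Mouse-PGK1_5 lies within that spread. With normexp correction the differences from the control were 1.01 log2 for Mouse-PGK1_5, 0.7 for Mouse-PGK1_3, 0.58 for Mouse-GAPDH_3 and 0.4 for Mouse-GAPDH_5. The main values were 1.49, 1.03, 0.84 and 0.67. Quantile normalization gave 1.45, 0.88, 0.67 and 0.37. In the brightest of 10 brightness groups, the median difference from the control was 0.22 log2, and these probes were not compared with others of like brightness. The SD between the 8 to 10 spots of each probe was 0.05 to 0.11 log2. In the Th2 model against the control, Mouse-GAPDH_5 differed by -0.29 log2, Mouse-GAPDH_3 by -0.07, Mouse-PGK1_3 by -0.08 and Mouse-PGK1_5 by 0.14, and centring on the spike-in probes turned the last to -0.44. Between the models, the 4 probes were 1.88-fold to 2.54-fold higher in the Th17 model, and centring on the spike-in probes brought the Mouse-GAPDH_3 and Mouse-GAPDH_5 differences to -0.13 and -0.08 log2.

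**Figure D2:**
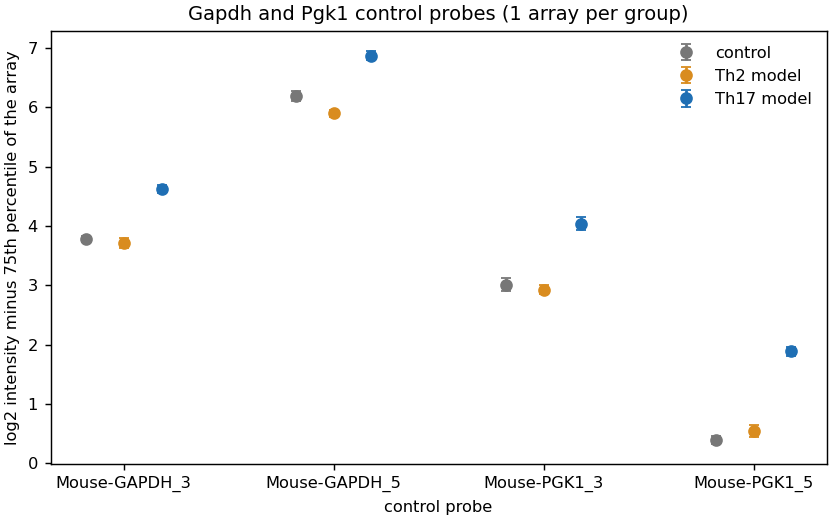
Levels of the mouse Gapdh and Pgk1 control probes (horizontal axis) on the control, Th2 model and Th17 model arrays, as log2 intensity minus the array's 75th percentile (vertical axis), with the mean of 8 to 10 spots of 1 array as point and the SD between spots as bar. The Th17 model lies highest for each probe, by 0.67 to 1.49 log2 above the control, and lies below the control where arrays are centred on the mean of 6 spike-in probes, whose own shifts ran from 0.3 to 1.26 log2.

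The probes fall into 3 families by name: 39430 named A_51 to A_66, 15955 named A_30 and 35803 named mmu. In the Th17 model against the control, the median difference was 0.18 log2 for A_51 to A_66 probes, -0.06 for A_30 probes and -0.03 for mmu probes. Of the A_51 to A_66 probes past 2-fold, 73.5% were higher in the Th17 model, against 41.5% of A_30 and 41.3% of mmu probes. In the Th2 model against the control, the medians were -0.03, 0.04 and 0.11, and 68.7%, 74.0% and 78.9% of the probes past 2-fold were higher. Between the models, A_51 to A_66 probes had a median of 0.22, A_30 probes of -0.05 and mmu probes of -0.12, and 63.1%, 20.2% and 16.7% of those past 2-fold were higher in the Th17 model. The contrast of A_30 with A_51 to A_66 probes was -0.24 in the Th17 model against the control, and that of mmu probes was -0.21. Centring on the spike-in probes moved the medians of all families by -1.63 in this comparison, -0.59 in the Th2 model against the control and -1.04 between the models. Centring cannot move the contrast between families. Quantile normalization gave -0.21 and -0.18, and no background correction gave -0.06 and -0.01.

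**Figure D3:**
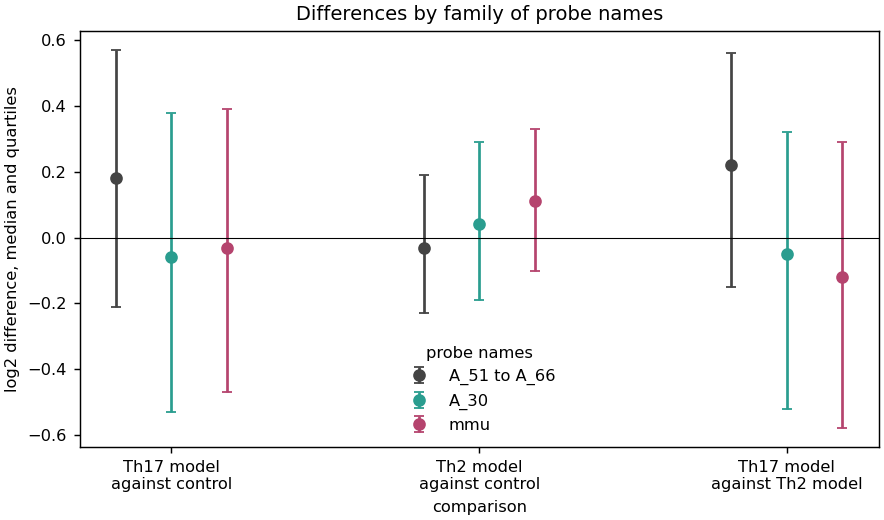
Median log2 difference (points) and quartiles (bars) of probes detected on both arrays, by comparison (horizontal axis) and family of probe names, with 1 array per group. In the Th17 model against the Th2 model, A_51 to A_66 probes have a median of 0.22, A_30 probes of -0.05 and mmu probes of -0.12, and centring on the spike-in probes, which moves every difference by -1.04, puts all 3 medians below 0.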

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

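The tests of slide, position, array brightness, spike-in amount, probe brightness and the dimmer probes' background were chosen only after the result was seen, while that of noise in dim spots was written first. Those of averaging of spots and of the brighter probes' background were written before their values were computed, but on families and a brightness split chosen after the data were seen.

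The spike-in probes drew a closer look because they lie outside the lung RNA measured in the comparisons and were brighter on the Th17 model array than on the control array. All 6 spike-in probes well above background on the 3 arrays, of 10 on the array, were higher there, by a mean of 0.86 log2 before scaling. The 75th percentile of the lung RNA probes differed by -0.77 in the same comparison, so the lung signal stood 3.1-fold lower against the spike-ins. In this comparison the slide cannot be told apart from the group. Within slide 1, the lung signal stood 2.06-fold lower in the Th17 model than in the Th2 model. In the Th2 model against the control it stood 1.5-fold lower. A dimmer array would lower both. The spike-in shift of 0.86, with an SD between spots of at most 0.17, argues against array brightness as the sole cause. However, the bright corner control spots shifted by -0.55, in the direction of the lung signal. They shifted by -0.41 in the Th2 model against the control and by -0.14 between the models on 1 slide. An unequal amount of spike-in for the RNA labelled may be the cause: the shifts ran from 0.3 to 1.26, a spread of 0.96 where a single factor would move all probes alike, but the amounts used are not recorded and this stays open, as does the model itself, which was not tested.

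The Th17 model array lay farther from the other arrays than they lay from each other. Between the 2 arrays of 1 slide, the SD of differences was 1.85 times that of the Th2 model against the control across slides, which argues against the slide as the cause. In the brightest of 5 groups of probes, the SD against the control was 2.16 times that of the Th2 model, which argues against noise in dim spots. The probes on 2 spots were grouped apart. In their brightest group, spots of a pair differed by 2-fold in 0.09% of cases on the Th17 model array. The A_51 to A_66 probes have no such pairs. Only 0.82% of the variance lay between 96 tiles of the array. The processed intensity was already detrended within the array, which can remove such a pattern, so this share cannot decide on a regional fault. A regional fault, the model, the mouse or mice behind 1 array, and RNA quality or amount remain open and may each contribute. The files' quality measures part the arrays the same way, with 0 of 10 out of range on the Th17 model array against 3 and 4 on the others.

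In the Th17 model against the control, A_30 and mmu probes lay lower than A_51 to A_66 probes. Matching on brightness kept 1.19 times the contrast or more, 1 spot per probe kept 0.89 of it or more, and the contrast between the models on 1 slide was -0.27 or lower, which argues against probe brightness, averaging and slide. In the brighter 50% of probes, leaving out the background correction kept 0.82 of the contrast or more, which argues against the background there. In the dimmer 50%, it kept at most 0.25 of the contrast while 0.56 of the SD was kept, a ratio of 0.45. This setting compresses the differences of dim probes by construction, and the SD covers all families, which differ in brightness. The ratio therefore cannot decide whether background correction causes the contrast among dim probes, and it stays a possible cause there. What the families measure was not tested, so a difference between classes of RNA in the Th17 model remains an open hypothesis for the brighter probes.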

How the results depend on the processing

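The alternatives chosen only after the data were seen were a higher floor, bounds only in the direction of detection, every spot above background, and the brighter 50% of probes. With 1 array per group, signal over background limits the counts, which moved with the background correction, the filter on dim probes and the floor, and no leave-one-out setting could be run. No paired analysis was possible because each group had 1 array and the result comes from no test. All gene-list alternatives and the median over all detected probes of a gene were not run, as the files and tables used here do not pair the probes with genes. Counts are given as higher and lower, first for the Th17 model against the control, then for the Th2 model against the control, then between the models, then for both models against the control. The main counts were 4738 and 5611, 1648 and 1147, 3272 and 6364, and 482 and 514. Of the 126 counts under other settings, 60 lay within 1.5 times and 66 did not. This tally is no measure of stability. It includes leaving out saturated probes, which could not move a count, and keeping outlier spots, which touched few spots. It also includes the 4-fold threshold, which counts larger differences only. The cause of a move was not tested unless the setting's construction shows it.

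Quantile normalization moved the Th2 model's higher count to 1076 and the shared higher count to 312. Normexp background correction gave 515 and 979, 22 and 99, 517 and 844, and 3 and 44. No background correction gave 1445 and 1287, 137 and 140, 715 and 1109, and 18 and 67. Both settings compress the differences of dim probes by construction. Only probes detected on both arrays gave 2667 lower in the Th17 model, 788 and 277, 2051 and 3310, and 254 and 76, since fewer probes were compared. No filter on dim probes gave 19810 higher in the Th17 model, 12254 and 2682, 6717 higher between the models, and 10307 and 1218. Centring on the spike-in probes gave 278 and 53935, 457 and 8361, 334 and 29326, and 14 and 7865, as it moved all differences by -1.63, -0.59 and -1.04. The 4-fold threshold gave 724 and 425, 225 and 119, 360 and 496, and 29 and 65. The higher floor gave 7575 and 3313, 2887 and 432, 4076 lower between the models, and 2203 and 189. Of its 7575 and 2887 higher probes, 3444 and 1700 were detected on the control array only and are no bounds, and without them 4131 and 1187 remained. Every spot above background gave 3240 lower in the Th17 model, 873 and 403, 3982 lower between the models, and 282 and 189. The brighter 50% of probes gave 1308 and 1132, 33 and 98, and 1250 and 1335, with no count for both models. No spot was saturated, so leaving saturated probes out moved nothing.

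Centring on the spike-in probes turned all 4 Gapdh and Pgk1 probes to lower in the Th17 model against the control, Mouse-PGK1_3 to -0.61 log2, Mouse-PGK1_5 to -0.14, Mouse-GAPDH_3 to -0.79 and Mouse-GAPDH_5 to -0.96. It also turned Mouse-PGK1_5 to -0.44 in the Th2 model against the control, and Mouse-GAPDH_3 and Mouse-GAPDH_5 to -0.13 and -0.08 between the models. Normexp correction left the 4 probes higher in the Th17 model than in the control, by 0.4 to 1.01 log2. Quantile normalization left them higher by 0.37 to 1.45 log2. The 12 differences of the probes named by ID kept their direction under each setting run, but their sizes moved. These probes were picked for the largest differences, which the settings could hardly turn, so the kept direction is no check on them. In the Th17 model against the control, A_51_P202331 lay between 8.01 and 10.69 log2, A_51_P110341 between 7.4 and 9.03, mmu_12354_PI428960544 between -5.31 and -1.78 and mmu_2823_PI428960544 between -5.28 and -1.97. In the Th2 model against the control, A_55_P2114367 lay between 2.6 and 5.07, A_51_P266876 between 1.36 and 3.51, mmu_12354_PI428960544 between -4.02 and -1.84 and A_55_P1997791 between -3.76 and -1.81. Between the models, A_51_P110341 lay between 7.46 and 8.51, mmu_31471_PI428960544 between 5.7 and 6.75, A_55_P2114367 between -4.79 and -1.98 and A_51_P367866 between -4.64 and -1.86. Of the 60 contrasts of probe families under other settings, 18 came from centring, which cannot move them. Of the other 42, 34 moved by less than 0.1 log2 and 8 by more, all 8 of them under normexp or no background correction. Under these settings every contrast with the Th17 model array moved. Against the control, normexp correction left -0.05 for A_30 and -0.02 for mmu probes. The contrasts of the Th2 model against the control were 0.07 and 0.14 in the main setting. A limit of 0.1 says little about contrasts of that size.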

Other observations

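The sets in this part were chosen after the differences were seen, and no test was planned for them. Among probes detected on all arrays, 15 were at least 16-fold higher in the Th17 model than in the control, 14 of them A_51 to A_66 probes and 1 an mmu probe. In the Th2 model, their median difference from the control was 0.34 log2, with 9 of the 15 higher and 1 at least 2-fold higher. Of the 196 probes at least 4-fold higher in the Th17 model, 136 were higher in the Th2 model too, with a median of 0.33 log2, and 35 were at least 2-fold higher. Over all probes detected on both arrays, the Th2 model's median difference from the control was 0.032 log2. It was 0.35 in the dimmest of 10 brightness groups and -0.02 in the brightest. The sets here were not matched on brightness, so their medians have no like reference. The 100 probes at least 4-fold lower in the Th17 model had a median of -0.07 log2 in the Th2 model, with 57 lower and 17 at least 2-fold lower.

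Seen from the Th2 model, and again among probes detected on all arrays, 10 probes were at least 4-fold higher than in the control, and all 10 were higher in the Th17 model, 8 of them by at least 2-fold. Of the 17 probes at least 4-fold lower in the Th2 model, 13 were lower in the Th17 model and 10 by at least 2-fold. Both comparisons share the control array, so a probe with an unusual value there enters both.

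Of the 40 probes on 10 spots, 19 were detected on both arrays of the Th17 model against the control, and 3 of these were at least 2-fold different. None of the 22 detected in the Th2 model against the control passed 2-fold. The median SD between their spots was 0.13 log2 on the Th17 model array.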
